A study of Mus musculus with 18 samples.

How the data were processed

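Total RNA from whole colon, rinsed and snap-frozen, was sequenced on a DNBSEQ instrument, per the labels' protocols. The authors deposited 1 table of FPKM for 18349 genes in 18 libraries, with NCBI gene identifiers and values rounded to 2 decimals. The submitters' processing notes name the genome build mm10. The aligner, the program that estimated FPKM, the annotation and any filter on reads are not given in the sources used here. Libraries were assigned to the Control, DSS, ZJ316 (WT), ZJ316-KO (KO) and ZJ316-COM (COM) groups from their titles. The labels' protocol divides 50 DSS-treated mice into 5 groups but names 4 of them, and 10 mice were controls.

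FPKM is already scaled to the library and to transcript length, so tests for read counts were not used. Library totals ranged from 517933 to 558590 FPKM. No pair of libraries shared more than 0.777% of identical values, so none was taken for a copy of another. Mitochondrially encoded genes and segments of immunoglobulin and T cell receptor genes were not analysed here. Of the gene identifiers, 18230 were matched to symbols in the RefSeq table of assembly GRCm38.p6, which also gave coordinates, and 119 were not matched.

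Values were transformed to log2(FPKM + 1). Fold changes on this scale understate the change of genes with low FPKM. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 13263. All 18 libraries entered 1 linear model of 5 groups in limma 3.58.1 (R 4.3.3) with moderated variances and a mean-variance trend. The 10 contrasts were tested two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, with no fold threshold. Before use, with 200 simulated changes, the model recovered 88.1% of 2-fold changes in DSS against Control and 86.6% in WT against DSS. Of 1.5-fold ones it found 62.7% and 70.1%. Recovery on real data is unknown.

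Of 46 gene lists of pathways and cell types, 45 had at least 3 tested members. They were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. At the preset correlation 142 of 450 tests passed, 83 upward and 59 downward, and with an estimated correlation 0 did. Member genes were also adjusted over the list alone. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise.

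Genes were named by a rule. In each comparison it took called genes whose groups did not overlap, with a mean of at least 5 FPKM in the higher group, and from these the 12 with the largest absolute log2 fold change in each direction. Predicted genes, clone names and pseudogenes were left out. Where fewer than 3 genes passed in a direction, the 5 with the smallest p were named in their place. From each list described, up to 4 members were named, called ones with the largest change first and then those with the smallest p. The purine and histidine lists were described in every comparison in this way. Some genes that the rule takes are not reported here.

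Changes of each strain against DSS were correlated across genes with the change of DSS against Control and with each other. As these comparisons share libraries, the same values were computed for 100 draws of simulated unchanged groups, and shares of opposite signs also, chosen after seeing the data, with the observed DSS change in all groups of DSS-treated mice. Alternatives tried were a pseudocount of 0.1, no filter (18231 genes), a filter of 5 FPKM in 3 libraries (9854 genes), quantile normalization, rescaling to TPM, only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. Removal of a trend on transcript length and GC content (GENCODE M21 gene models, which covered 98.9% of tested genes) and the exclusion of libraries that stood apart in marker genes were added after seeing the data.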

Results

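Gene expression was measured by bulk RNA sequencing of whole colon from male C57BL/6 mice. The 18 libraries fall into 5 groups. Mice of the Control group (n = 3) drank water. All others drank 2.5% dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium, for 7 days. After this the DSS group (n = 3) was gavaged with PBS for 5 weeks. The remaining groups were gavaged over the same period with a Lactobacillus plantarum strain, a lactic acid bacterium: ZJ316 (WT, n = 4), ZJ316-KO (KO, n = 4) or ZJ316-COM (COM, n = 4). The labels do not say what KO and COM stand for, and their protocol mentions no gavage of Control mice. The labels number the libraries without tying them to single animals, so p-values measure only the spread between these samples. Expression values are FPKM (fragments per kilobase of transcript, scaled to library size), and 16446 to 16859 genes lay above 0 in a library. The number of reads is unknown. Steps between low values had relative sizes of 0.978 to 1.01. Only steps of similar size were compared, so these cannot show whether depths were equal. Changes are given as log2 fold change of FPKM + 1 ± SE from limma, with adjusted p, and levels as mean ± SD. An adjusted p given for a gene list is that of camera. Every gene named as passing had no overlap between the libraries of its 2 groups, unless it is given as a member of a gene list.

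Single libraries stood apart from the others of their group in genes of other tissues or gut regions. Pancreatic acinar genes, which encode digestive enzymes, had a mean log2(FPKM + 1) of 11.1 in DSS 1, 8.59 in DSS 3 and 9.55 in KO 3, and at most 1.22 in the other 15 libraries. The distal gut Hox genes, which mark position along the intestine, had a mean of 1.15 in Control 3, 2.26 in KO 2 and 2.81 in DSS 3, against 3.60 to 4.58 elsewhere. Hoxb13, expressed in the most distal colon, lay at 0.76 FPKM in Control 3 and at 79.3 FPKM or more in every other library. Adipocyte genes had a mean of 5.29 in Control 3 and fatty acid oxidation genes one of 5.32, the highest of all libraries. B cell markers had a mean of 0.42 in Control 3 and 1.90 to 3.65 elsewhere. Squamous epithelium genes, which are expressed in stratified epithelia such as the anal canal, had a mean of 4.02 in DSS 2, 4.01 in COM 3, 3.32 in WT 2, 2.63 in WT 4 and 2.46 in KO 3, and at most 1.34 elsewhere. Counts without the acinar-rich, the squamous-rich or the low-Hox libraries (Control 3 and KO 2), or after correction for a trend on transcript length and GC content, were chosen after seeing the data.

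**Figure D1:**
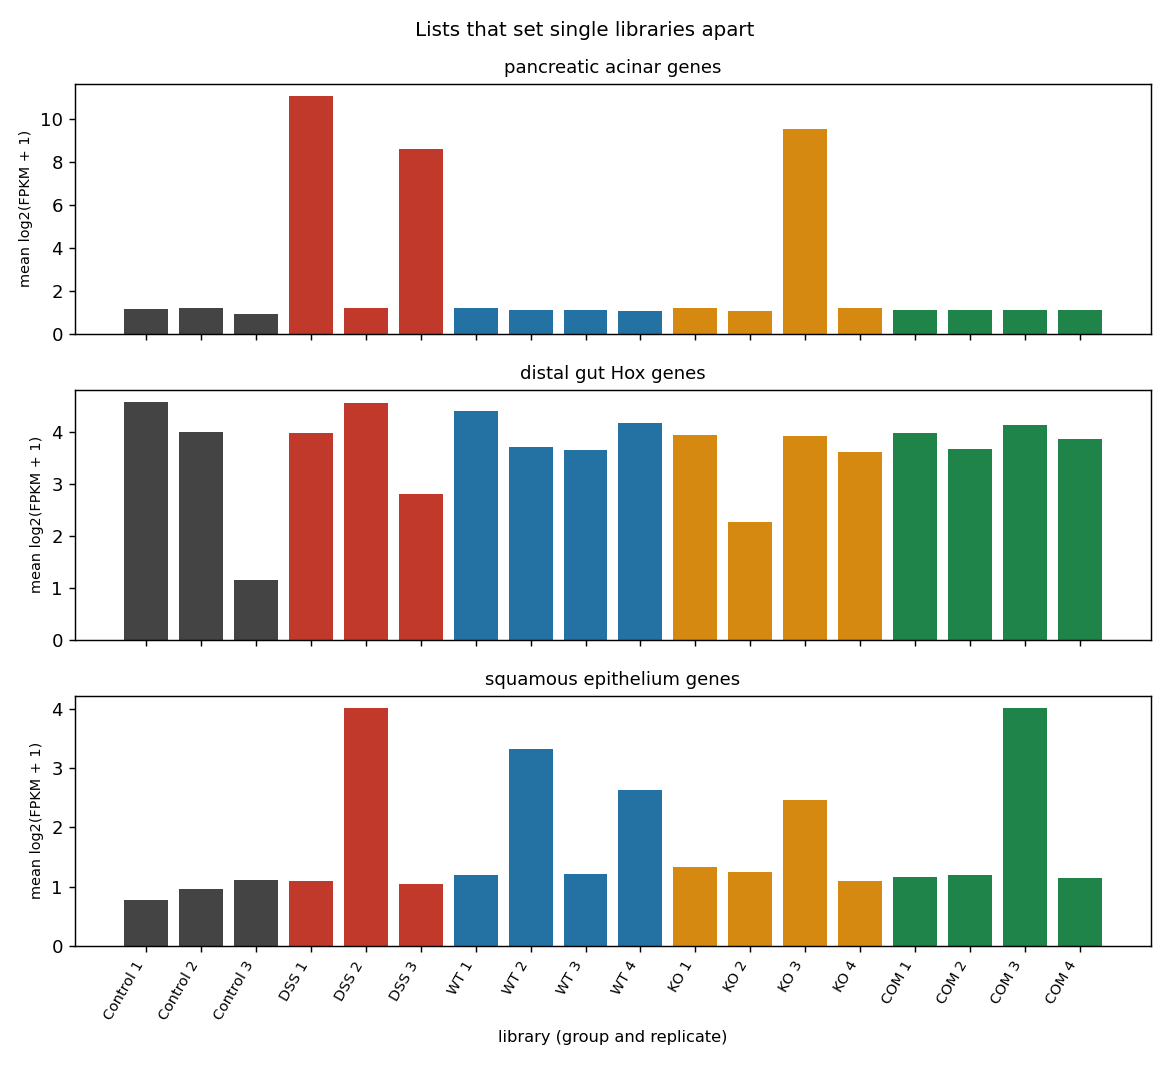
Mean log2(FPKM + 1) of 3 gene lists (bars) in each of the 18 libraries, coloured by group. Pancreatic acinar genes reached 8.59 or more in DSS 1, DSS 3 and KO 3, distal gut Hox genes were lowest in Control 3, and squamous epithelium genes reached 2.46 or more in DSS 2, WT 2, WT 4, KO 3 and COM 3.

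The comparison of DSS with Control asked how the colon of DSS-treated, PBS-gavaged mice differed from that of untreated mice. Among the called genes taken by the naming rule, the largest increase was that of Clca4b, a member of the calcium-activated chloride channel regulator family with close paralogs (gene ID 99709, chromosome 3, 144910921 to 144932529, GRCm38.p6). It rose by 4.86 ± 0.62 (adjusted p = 7.07e-04), from 7.47 ± 7.09 FPKM in Control to 204 ± 65.6 FPKM in DSS (n = 3 each). Ang4, a secreted antimicrobial ribonuclease of the gut epithelium (chromosome 14, 51763892 to 51773590), rose by 3.91 ± 1.11 (adjusted p = 0.0256), from 227 ± 355 to 809 ± 179 FPKM. S100a8, a subunit of the neutrophil protein calprotectin, was listed at 0 in all 3 Control libraries and lay at 5.44 ± 3.46 FPKM in DSS (adjusted p = 0.0120). Its partner S100a9 rose by 2.66 ± 0.80, and the neutrophil-attracting chemokine Cxcl5 rose by 2.60 ± 0.77 (adjusted p = 0.0324 and 0.0311). Other genes that rose included Khdc1a (3.54 ± 0.47), Glycam1, a ligand of L-selectin (2.74 ± 0.57), Aldh1a3, which makes retinoic acid (2.43 ± 0.57), the adhesion receptor Adgrf1 (2.38 ± 0.34), the atrial myosin light chain Myl7 (2.22 ± 0.54), the protease inhibitor Serpina3n (2.20 ± 0.29) and the annexin Anxa8 (2.18 ± 0.61). Without Control 1 the value of Ang4 was 2.30, and without Control 3 that of Anxa8 was 1.17.

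Among the genes that fell in DSS, the cytochrome P450 gene Cyp2c55 fell by 1.90 ± 0.57 (adjusted p = 0.0344), from 1339.7 ± 1571 to 222 ± 33.6 FPKM. The phenol sulfotransferase gene Sult1a1 fell by 1.22 ± 0.22 (adjusted p = 0.00300). The carboxylesterase genes Ces2a and Ces2c fell by 1.19 ± 0.20 and 1.19 ± 0.24, and the pyrimidine-degrading Dpyd fell by 1.27 ± 0.40. The interferon-related genes Irf7, Ifit1bl2 and Apol9a fell by 1.18 ± 0.35, 1.26 ± 0.29 and 1.53 ± 0.47. The intestinal peptidase Naaladl1, the MHC class I gene H2-Q2, Ppfia3 and the calmodulin-binding Pcp4 fell by 1.52 ± 0.42, 1.31 ± 0.35, 1.59 ± 0.33 and 1.82 ± 0.56. Ces2a, Ces2c and H2-Q2 have close paralogs, so their single values are uncertain. Without Control 3, the library with low Hox genes, Cyp2c55 stood at -0.93, Dpyd at -0.82 and H2-Q2 at -0.80.

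By gene list, markers of vessels, macrophages and connective tissue were higher in DSS. All 12 macrophage markers rose (12 adjusted over the list alone, adjusted p = 1.79e-07), among them the complement genes C1qc (1.48 ± 0.35) and C1qb (1.46 ± 0.32) and the growth factor receptor gene Csf1r (1.33 ± 0.26). Of 10 endothelial genes 9 rose (9 adjusted over the list alone, adjusted p = 2.00e-09), with Cldn5 at 1.25 ± 0.19, Pecam1 at 1.17 ± 0.13 and Cdh5 at 1.03 ± 0.14. Of 14 fibroblast and collagen genes 12 rose (12 adjusted over the list alone, adjusted p = 2.45e-07), including Dcn (1.39 ± 0.24), Col1a2 (1.15 ± 0.21) and Col3a1 (1.10 ± 0.25). Of 14 matrix proteases and inhibitors 9 rose (10 adjusted over the list alone, adjusted p = 2.28e-06), led by Mmp10 (2.12 ± 0.35), Mmp3 (1.62 ± 0.25) and Mmp13 (1.39 ± 0.28). These 4 lists had adjusted p = 0.259 to 0.370 with an estimated correlation. Without Control 3 C1qb stood at 0.96 and C1qc at 0.89.

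Leukocyte lists were also higher in DSS than in Control. The neutrophil list rose in 5 of 10 genes (6 adjusted over the list alone, adjusted p = 0.00207), with the receptor gene Csf3r at 1.19 ± 0.28. Its mean was 2.77 in the squamous-rich DSS 2, against 1.60 in DSS 1 and 2.10 in DSS 3, and S100a8 and S100a9 lost their calls without DSS 2 or DSS 3, S100a9 also without Control 2 or Control 3. The cytokine list rose in 2 of 11 (4 adjusted over the list alone, adjusted p = 0.00613), with Il1b at 1.73 ± 0.35. Of 7 plasma cell markers 5 rose (5 adjusted over the list alone, adjusted p = 0.0135), including Jchain (1.97 ± 0.58), Mzb1 (1.84 ± 0.48) and Derl3 (1.49 ± 0.35), which stood at 0.96, 0.997 and 0.93 without Control 3. Of 12 T and NK cell markers 4 rose (6 adjusted over the list alone, adjusted p = 0.0260), with Cd4 at 1.38 ± 0.31 and Cd3g at 0.97 ± 0.23. This list lost its call without Control 1. Of 14 NF-kB targets 5 rose (6 adjusted over the list alone, adjusted p = 0.0135), among them the adhesion molecule genes Vcam1 (1.40 ± 0.29) and Icam1 (0.997 ± 0.24). The call was lost without Control 1 or Control 3. Of 7 mast cell markers 3 rose (5 adjusted over the list alone, adjusted p = 0.0345), with the protease genes Mcpt1 at 1.30 ± 0.37 and Cpa3 at 0.60 ± 0.16, a call lost without Control 1 or DSS 1 and after quantile normalization. The B cell list was called higher (adjusted p = 0.00842) with 0 of 10 genes past the threshold over all genes and 9 adjusted over the list alone. Cr2 stood at 1.26 ± 0.45 and Blk at 1.09 ± 0.39, and the call was lost without Control 3, the library with few B cell transcripts. The acinar list was likewise called (adjusted p = 0.00114) with 0 of 12 genes over all genes and 12 adjusted over the list alone, at 6.09 ± 2.18 for Cpb1 and 6.28 ± 2.25 for Try4, which has near-identical copies. Its signal came from DSS 1 and DSS 3, and the call was lost without DSS 1. In these 8 lists the test gave adjusted p = 0.315 to 0.613 with an estimated correlation.

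Lists of energy metabolism, muscle, nerve and absorptive cells were called lower in DSS. Of 20 nuclear oxidative phosphorylation genes 13 fell (19 adjusted over the list alone, adjusted p = 2.23e-12), including the electron carrier gene Cycs (-0.53 ± 0.17) and the cytochrome c oxidase subunit genes Cox4i1 (-0.52 ± 0.11) and Cox7b (-0.48 ± 0.10). Of 13 xenobiotic and bile acid genes 6 fell (6 adjusted over the list alone, adjusted p = 1.65e-05), with the glutathione transferase gene Gsta1 at -0.92 ± 0.28 and Cyp3a13 at -0.79 ± 0.19. Of 12 enteric neuron and glia genes 4 fell (7 adjusted over the list alone, adjusted p = 6.29e-05), for example Snap25 (-0.76 ± 0.17) and Uchl1 (-0.74 ± 0.23). Of 12 smooth muscle genes 4 fell (5 adjusted over the list alone, adjusted p = 9.05e-05), with Mylk at -0.57 ± 0.14, Des at -0.54 ± 0.14 and Cnn1 at -0.48 ± 0.14. The brush border genes Cdhr5 (-0.55 ± 0.10) and Vil1 (-0.42 ± 0.09) were the 2 of 16 absorptive colonocyte genes that fell (2 adjusted over the list alone, adjusted p = 1.62e-04). Of 13 fatty acid oxidation genes 1 fell, Acadm (-0.42 ± 0.10, 1 adjusted over the list alone, adjusted p = 0.00803, lost without Control 3). Of 18 interferon genes 1 fell, Irf7 (0 adjusted over the list alone, adjusted p = 0.0406, lost without Control 1, Control 3 or DSS 2 and after quantile normalization). With an estimated correlation these 7 lists had adjusted p = 0.259 to 0.791. Without Control 3 Cycs stood at -0.34 and Gsta1 at -0.56.

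**Figure D2:**
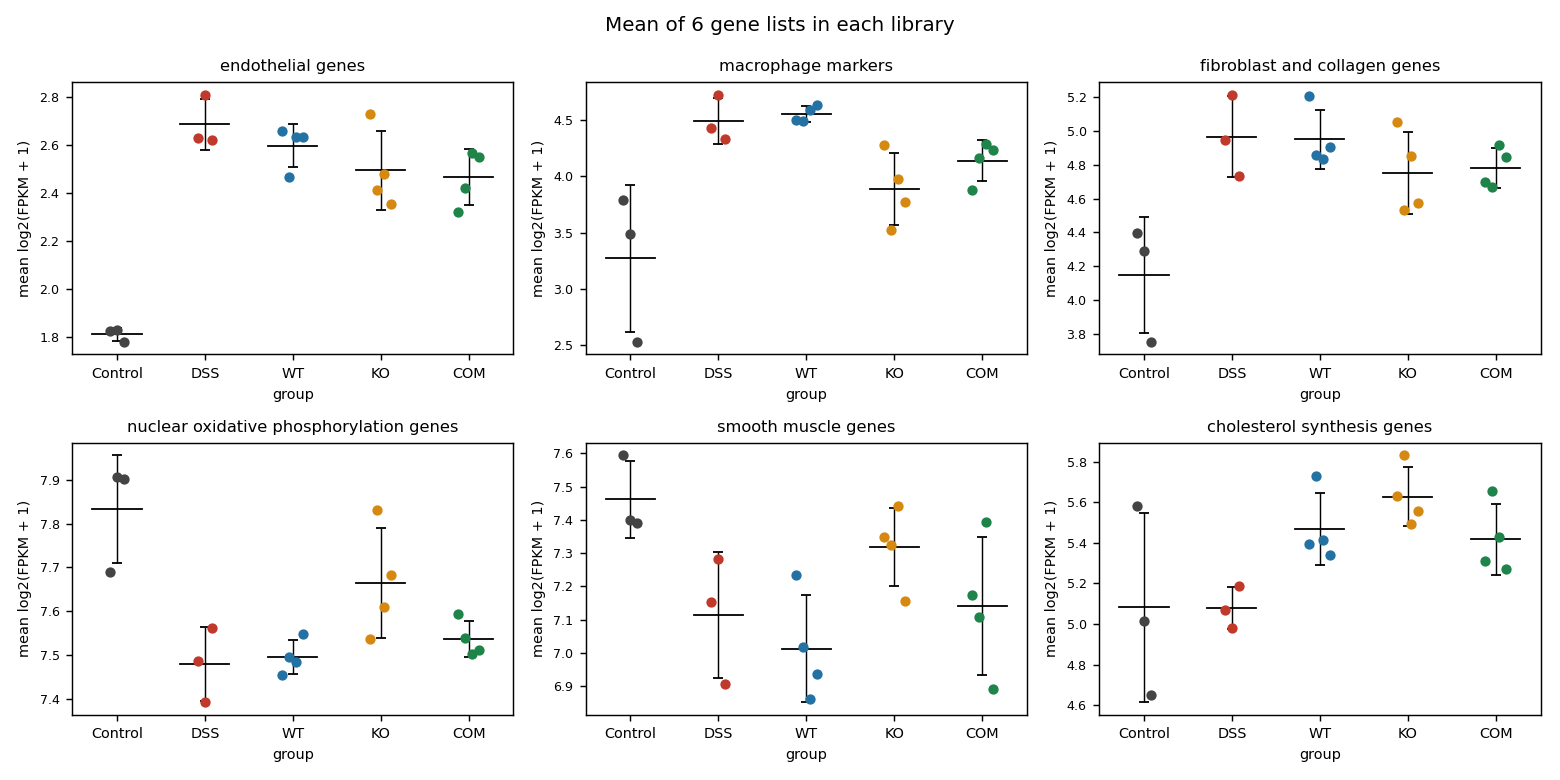
Mean log2(FPKM + 1) of 6 gene lists in each library (points), with the group mean (line) and SD (bars) for Control, DSS, WT, KO and COM. The y axes do not start at 0. Endothelial, macrophage and fibroblast lists lie lowest in Control, and the nuclear oxidative phosphorylation and smooth muscle lists lie highest there.

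The series title names purine and histidine metabolism, so both lists were examined in every comparison. In DSS against Control the purine list was not called as a set (adjusted p = 0.374), but 3 of its 26 genes rose and 1 fell, also when adjusted over the list alone (3 and 1). The ectonucleotidase gene Entpd1 rose by 1.08 ± 0.21, and Paics and Atic, which act in purine synthesis, rose by 0.61 ± 0.20 and 0.37 ± 0.11. Entpd8, another ectonucleotidase gene, fell by 0.63 ± 0.16. Of 8 histidine and histamine genes 1 fell, the carnosine dipeptidase gene Cndp2, by 0.58 ± 0.10 (adjusted p = 0.00288, 1 adjusted over the list alone, camera adjusted p = 0.345). Hnmt, which inactivates histamine, stood at -0.25 ± 0.16, Maob at -0.33 ± 0.21 and Hars2 at 0.11 ± 0.07, none of them past the threshold. Without Control 3 Paics stood at 0.30.

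Limma called 2243 of 13263 genes between DSS and Control, 1539 higher and 704 lower. The split depended on the scaling: 916 higher and 1058 lower after quantile normalization, 1815 and 506 after rescaling to TPM, and 1199 and 925 after correction for length and GC content. The count was 3662 without Control 1, 1461 without Control 3, 1266 without DSS 2 and 1393 without DSS 3, and 426 without the acinar-rich libraries or 309 without the squamous-rich ones. With a fit of the DSS and Control libraries alone 0 genes passed in limma, where 2643 had an unadjusted p under 0.05. Of the 83 named genes that passed, 47 passed with each library left out, and the call was lost for 28 without Control 3, 27 without DSS 3, 23 without DSS 1 or without DSS 2, 6 without Control 2 and 2 without Control 1.

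The WT group against Control asked how DSS-treated mice given ZJ316 differed from untreated mice. Clca4b again had the largest change of the genes named, with 5.59 ± 0.58 and 358 ± 154 FPKM in WT (adjusted p = 2.17e-04). Khdc1a (4.04 ± 0.44), Adgrf1 (2.83 ± 0.32), Anxa8 (2.78 ± 0.57) and Aldh1a3 (2.70 ± 0.53) rose too. So did Cxcl5 (3.25 ± 0.72), the acute-phase gene Lrg1 (3.05 ± 0.51), inducible nitric oxide synthase Nos2 (2.91 ± 0.54), the lipopolysaccharide-binding protein gene Lbp (2.58 ± 0.39), the leukocyte protease inhibitor Slpi (2.56 ± 0.48), S100a9 (2.37 ± 0.74) and the kallikrein gene Klk15 (2.59 ± 0.77). Cyp2c55 fell by 2.08 ± 0.54, and the manganese exporter gene Slc30a10 fell by 2.18 ± 0.57. Other genes that fell were Phospho1 (-1.95 ± 0.60), Mettl7b (-1.85 ± 0.51), the glucuronosyltransferase Ugt1a6b (-1.78 ± 0.39), the carboxylesterase Ces1d (-1.73 ± 0.38), Dpyd (-1.68 ± 0.37) and the steroid dehydrogenases Hsd3b2 (-1.58 ± 0.47) and Hsd3b3 (-1.57 ± 0.45). Ppfia3 (-1.73 ± 0.31), the RNA-binding protein gene Igf2bp2 (-1.57 ± 0.48) and the heat shock gene Hspa1a (-1.80 ± 0.47), which has a near-identical copy, also fell. Without Control 3 Anxa8, Cyp2c55, Phospho1, Mettl7b, Hsd3b2, Hsd3b3, Igf2bp2 and Hspa1a stood at 1.76, -1.12, -0.88, -1.10, -0.88, -0.92, -0.99 and -0.95.

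The following 10 lists were called in WT against Control in the direction seen for DSS. All 12 macrophage markers rose (12 adjusted over the list alone, adjusted p = 9.39e-08), with Ms4a7 at 1.48 ± 0.20, C1qb at 1.48 ± 0.30 and Adgre1 at 1.40 ± 0.23. Of 10 endothelial genes 9 rose (9 adjusted over the list alone, adjusted p = 9.39e-08), with Pecam1 at 1.09 ± 0.12, Egfl7 at 1.03 ± 0.16 and Cdh5 at 1.01 ± 0.13. 11 of 14 fibroblast genes (13 adjusted over the list alone, adjusted p = 1.17e-06, Dcn 1.45 ± 0.23, Col3a1 1.15 ± 0.23) and 9 of 14 matrix proteases and inhibitors (12 adjusted over the list alone, adjusted p = 1.27e-05, Mmp10 2.15 ± 0.33, Mmp13 1.74 ± 0.26, Mmp3 1.61 ± 0.23) rose. Of 7 mast cell markers 5 rose (6 adjusted over the list alone, adjusted p = 0.00436), with Mcpt1 at 1.85 ± 0.35 and Mcpt2 at 1.38 ± 0.33, and so did 7 of 11 cytokine genes (10 adjusted over the list alone, adjusted p = 9.89e-04), with Il1b at 1.71 ± 0.33. Of the oxidative phosphorylation genes 15 of 20 fell (16 adjusted over the list alone, adjusted p = 2.82e-10), including Cox4i1 (-0.55 ± 0.10) and Uqcrq (-0.54 ± 0.12). Neuron and glia genes fell in 9 of 12 cases (11 adjusted over the list alone, adjusted p = 3.45e-06, Uchl1 -0.90 ± 0.21, Snap25 -0.75 ± 0.16) and smooth muscle genes in 7 of 12 (10 adjusted over the list alone, adjusted p = 6.32e-06, Des -0.74 ± 0.14, Mylk -0.66 ± 0.13). Of 13 xenobiotic genes 5 fell (6 adjusted over the list alone, adjusted p = 2.19e-04), with Ces2a at -1.29 ± 0.19. Each of the 10 kept its call with every library left out. Without Control 3 C1qb stood at 0.98. Also called were the neutrophil, plasma cell, T and NK cell and proliferation lists, higher in 6 of 10, 5 of 7, 4 of 12 and 3 of 18 genes (7, 6, 4 and 0 adjusted over the list alone), and the colonocyte and fatty acid oxidation lists, lower in 3 of 16 and 1 of 13 (3 and 1). They had adjusted p = 7.54e-04 to 0.0409. The 16 lists had adjusted p = 0.325 to 0.728 with an estimated correlation. The call was lost for T and NK cells without Control 1 or WT 4, for proliferation without Control 2, Control 3 or WT 2 and after rescaling to TPM, and for fatty acid oxidation without Control 3. Squamous epithelium genes were high in WT 2 and WT 4.

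In the purine list 8 of 26 genes rose and 1 fell in WT against Control (14 and 3 adjusted over the list alone), without a call of the list as a set (adjusted p = 0.0546). Entpd1 rose by 1.17 ± 0.20, the guanine deaminase gene Gda by 0.85 ± 0.20 and the xanthine dehydrogenase gene Xdh by 0.79 ± 0.20, whereas Entpd8 fell by 0.72 ± 0.15. Of 8 histidine and histamine genes 1 fell, Cndp2 by 0.54 ± 0.10 (1 adjusted over the list alone, adjusted p = 0.249), and Hnmt (-0.30 ± 0.15), Hars (0.14 ± 0.08) and Carns1 (-0.14 ± 0.13) did not pass. Limma called 3058 genes, 1951 higher and 1107 lower, against 1413 and 1485 after quantile normalization, 2617 and 822 after rescaling to TPM and 1540 and 1407 after correction for length and GC content. The TPM scaling alone moved the median of all genes to 0.10 in this comparison. The count was 4624 without Control 1, 1873 without Control 3, 1016 with the WT and Control libraries alone and 751 without the squamous-rich libraries. Of the 51 named genes that passed, 43 passed with each library left out, and the call was lost for 8 without Control 3, 6 without WT 1 or without WT 2 and 1 without Control 2, WT 3 or WT 4.

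In the KO group, Clca4b again had the largest change from Control of the genes named, and rose by 4.47 ± 0.58 to 174 ± 97.6 FPKM (adjusted p = 0.00185). The clock-controlled transcription factor gene Dbp (gene ID 13170, chromosome 7, 45705100 to 45710203) rose by 2.71 ± 0.30 (adjusted p = 9.12e-04). Nr1d1, a repressor within the circadian clock, rose by 2.26 ± 0.34, and Cry1, a repressor of the same oscillator, fell by 1.43 ± 0.19. Banp, which encodes a nuclear DNA-binding protein (gene ID 53325, chromosome 8, 121947972 to 122029260), fell by 1.28 ± 0.12 (adjusted p = 1.99e-04). Khdc1a (2.78 ± 0.44), Myl7 (2.59 ± 0.51), Anxa8 (2.15 ± 0.57), Adgrf1 (2.14 ± 0.32), Glycam1 (2.00 ± 0.53), Dhrs9 (1.95 ± 0.37), Ly6m (1.87 ± 0.27), the mast cell protease gene Mcpt1 (1.86 ± 0.35) and Clca3b (1.70 ± 0.28) rose. Ifit1bl2 (-1.84 ± 0.27), Naaladl1 (-1.80 ± 0.39), the growth factor gene Bmp3 (-1.25 ± 0.33), the endothelin gene Edn2 (-1.03 ± 0.28), H2-Q1 (-0.93 ± 0.23), Iyd (-0.92 ± 0.14), Ces2a (-0.97 ± 0.19), Ces2c (-0.92 ± 0.23) and Sult1a1 (-0.92 ± 0.20) fell. Clca3b, H2-Q1, Ces2a and Ces2c have close paralogs, so their single values are uncertain. Without Control 3 the values were 1.14 for Anxa8, -0.69 for Bmp3, -0.64 for Edn2 and -0.60 for Ces2c.

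Cholesterol synthesis and endothelial genes were among the lists higher in KO than in Control. Of 14 cholesterol synthesis genes 4 rose (8 adjusted over the list alone, adjusted p = 3.03e-06), among them Insig1 (0.88 ± 0.24) and Fdft1 (0.77 ± 0.18). Of 10 endothelial genes 9 rose (9 adjusted over the list alone, adjusted p = 5.80e-11), with Cldn5 at 0.90 ± 0.18 and Pecam1 at 0.88 ± 0.12. Of 14 matrix proteases and inhibitors 6 rose (12 adjusted over the list alone, adjusted p = 8.68e-08), with Mmp10 at 1.62 ± 0.33, as did 5 of 14 fibroblast genes (12 adjusted over the list alone, adjusted p = 9.50e-08), with Dcn at 1.15 ± 0.23 and Lum at 0.86 ± 0.16. Of 7 mast cell markers 5 rose (5 adjusted over the list alone, adjusted p = 6.60e-04), with Mcpt2 at 1.45 ± 0.33. Of 13 goblet cell and mucus genes 3 rose (3 adjusted over the list alone, adjusted p = 0.0375), namely Clca1 (1.21 ± 0.31), Fcgbp (1.16 ± 0.24) and Spink4 (1.03 ± 0.28). This call was lost without Control 1, Control 2 or KO 2 and after rescaling to TPM, and the other 5 lists kept theirs with each library left out. Without Control 3 Insig1 stood at 0.44, Clca1 at 0.70 and Fcgbp at 0.74, and without Control 1 Spink4 stood at 0.61. Also called higher were the macrophage, neutrophil, cytokine, antimicrobial and ribosomal protein lists (adjusted p = 1.53e-04 to 0.0454), with 0, 1, 1, 1 and 0 genes past the threshold and 3, 3, 1, 2 and 0 adjusted over the list alone. Each lost its call without Control 3 and, but for the macrophage list, without Control 1, and the ribosomal protein list turned lower without Control 3.

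Other lists were lower in KO than in Control. Of 13 xenobiotic genes 2 fell, Ces2a and Cyp3a13 (-0.77 ± 0.18; 4 adjusted over the list alone, adjusted p = 2.51e-04), and of 10 heat shock genes 1 fell, Hspa8 (-0.42 ± 0.12; 3 adjusted over the list alone, adjusted p = 0.0109). The oxidative phosphorylation list was called lower at a median of -0.18 (adjusted p = 2.47e-06, Cox4i1 -0.34 ± 0.10), as were the enteric neuron and glia (7.94e-04), interferon (0.00591), smooth muscle (0.0338) and fatty acid oxidation (0.0389) lists, all 5 with 0 genes by either adjustment. The oxidative phosphorylation list kept its call with each library left out, and the other 6 lost it without Control 3, where fatty acid oxidation turned higher. The interferon and smooth muscle lists lost it also without Control 1, smooth muscle without KO 4 and fatty acid oxidation without KO 1 or KO 4. The 18 lists called, higher or lower, had adjusted p = 0.145 to 0.819 with an estimated correlation.

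The purine list of KO against Control held 2 genes of 26 that rose (3 adjusted over the list alone, adjusted p = 0.142), Entpd1 by 0.73 ± 0.20 and Atic by 0.41 ± 0.10, beside Nt5c2 (0.34 ± 0.10) and Entpd8 (-0.32 ± 0.15), which did not pass. In the histidine list Cndp2 fell by 0.53 ± 0.10 (1 of 8 genes, 1 adjusted over the list alone, adjusted p = 0.125), and Hars (0.14 ± 0.08), Hrh1 (-0.17 ± 0.12) and Maob (-0.25 ± 0.20) did not pass. Limma called 682 genes, 489 higher and 193 lower, against 290 and 229 after quantile normalization, 591 and 121 after rescaling to TPM and 466 and 339 after correction for length and GC content. The count was 1591 without Control 1, 443 without Control 2, 254 without KO 1 and 420 without KO 3. It was 2 with the KO and Control libraries alone, 268 without the acinar-rich and 159 without the squamous-rich libraries. Of the 40 named genes that passed, 23 passed with each library left out, and the call was lost for 17 without Control 3, 16 without KO 1, 11 without KO 3, 9 without Control 2 or without KO 2, 8 without KO 4 and 1 without Control 1. Entpd1 stood at 0.47 without Control 3.

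In the COM group, clock genes were named beside Clca4b among the genes that differed from Control. Clca4b rose by 4.49 ± 0.58 (adjusted p = 0.00126). Dbp rose by 3.14 ± 0.30 (adjusted p = 2.50e-04), and Tef, a transcription factor of the same family, rose by 1.86 ± 0.24 (adjusted p = 0.00126). Nr1d1 rose by 2.66 ± 0.34. Cry1 fell by 1.81 ± 0.19 (adjusted p = 4.90e-04), and the clock activators Arntl and Npas2 fell by 0.98 ± 0.15 and 0.85 ± 0.15. The clock-linked gene Nfil3 fell by 1.08 ± 0.27. Khdc1a (3.68 ± 0.44), Anxa8 (2.38 ± 0.57), Adgrf1 (2.18 ± 0.32), Myl7 (2.12 ± 0.51), Inmt (2.09 ± 0.54), Aldh1a3 (2.03 ± 0.53), Nos2 (1.93 ± 0.54) and the chemokine gene Ccl8 (1.92 ± 0.32) rose. The calcium pump regulator gene Pln (-1.09 ± 0.28), Odf3b (-1.08 ± 0.23), Iyd (-0.90 ± 0.14), the efflux transporter gene Abcg2 (-0.83 ± 0.20), Sult1a1 (-0.75 ± 0.20), the cell cycle inhibitor gene Cdkn2b (-0.74 ± 0.11) and Tm6sf2 (-0.72 ± 0.17) fell. Without Control 3 Anxa8 stood at 1.36.

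The clock list of COM against Control had 8 of 14 genes higher and 3 lower (8 and 3 adjusted over the list alone, adjusted p = 0.0185, lost without Control 3 and after rescaling to TPM). Of 20 oxidative phosphorylation genes 10 fell (14 adjusted over the list alone, adjusted p = 8.81e-13), with Uqcrq at -0.52 ± 0.12 and Cox6c at -0.50 ± 0.12. Of 10 endothelial genes 7 rose (9 adjusted over the list alone, adjusted p = 1.93e-09), with Cdh5 at 0.91 ± 0.13 and Pecam1 at 0.90 ± 0.12. Of 12 macrophage markers 8 rose (11 adjusted over the list alone, adjusted p = 1.30e-06, C1qc 1.16 ± 0.33, Ms4a7 1.10 ± 0.20), and so did 7 of 14 fibroblast genes (13 adjusted over the list alone, adjusted p = 6.03e-07, Dcn 1.37 ± 0.23) and 7 of 14 matrix proteases and inhibitors (10 adjusted over the list alone, adjusted p = 7.50e-06, Mmp10 1.38 ± 0.33, Mmp3 1.31 ± 0.23). Without Control 3 C1qc stood at 0.58. The neutrophil, cytokine, T and NK cell, mast cell and cholesterol lists were called higher too, with 0, 2, 3, 2 and 1 genes past the threshold (4, 2, 3, 3 and 1 adjusted over the list alone), and the colonocyte, smooth muscle, enteric neuron and xenobiotic lists lower, with 1, 3, 1 and 2 (1, 7, 4 and 2). They had adjusted p = 1.79e-05 to 0.0339. Neutrophil, colonocyte and xenobiotic lists lost their call without Control 3, mast cells without Control 1, T and NK cells without COM 2 and cholesterol without Control 2, Control 3 or COM 2. The 15 lists given had adjusted p = 0.275 to 0.753 with an estimated correlation. Squamous epithelium genes were high in COM 3 alone among the COM libraries.

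In the purine list of COM against Control Entpd1 rose by 0.82 ± 0.20 and Entpd8 fell by 0.56 ± 0.15 (1 and 1 of 26 genes, the same counts adjusted over the list alone, adjusted p = 0.299), beside Paics (0.56 ± 0.18) and Nt5c2 (0.29 ± 0.10), which did not pass. In the histidine list Cndp2 fell by 0.46 ± 0.10 (1 of 8 genes, 1 adjusted over the list alone, adjusted p = 0.336) and Hrh1 stood at -0.16 ± 0.12. Limma called 1008 genes, 697 higher and 311 lower, against 402 and 429 after quantile normalization and 1166 and 191 after rescaling to TPM. The count was 2302 without Control 1, 531 without Control 2, 402 without COM 3 and 486 without COM 4. It was 15 with the COM and Control libraries alone and 63 without the squamous-rich libraries. Of the 36 named genes that passed, 19 passed with each library left out, and the call was lost for 15 without Control 2, 13 without COM 3 or without COM 4, 10 without Control 3, 6 without COM 2 and 1 without Control 1 or without COM 1.

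The WT group against DSS asked whether gavage with ZJ316 changed the colon of DSS-treated mice. Limma called 0 genes, and 633 had an unadjusted p under 0.05, against 663 from chance. The largest difference among the genes with the smallest p was that of the phospholipase gene Pla2g4c, at -3.40 ± 0.81, with 25.3 ± 13.4 FPKM in DSS and 1.75 ± 2.21 FPKM in WT (adjusted p = 0.9996). Gsdmc2, a gasdermin gene of the gut epithelium, stood at -1.26 ± 0.27. Also lower in mean without passing were Trim35 (-0.34 ± 0.08), Dennd11 (-0.58 ± 0.13) and Gimap1 (-0.50 ± 0.13), and higher in mean were Ccdc116 (0.45 ± 0.10), Tamm41 (0.41 ± 0.11), Cdkn3 (0.36 ± 0.10), Cds1 (0.23 ± 0.06) and Rac1 (0.19 ± 0.05). Without the squamous-rich libraries, which left the acinar-rich DSS 1 and DSS 3 as the DSS group, limma called 27 genes, 0 higher and 27 lower.

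Camera called 11 lists between WT and DSS at the preset correlation. All 14 cholesterol synthesis genes had a positive change, with a median of 0.43 and 0 genes past the threshold over all genes or adjusted over the list alone (adjusted p = 1.03e-10). Sqle stood at 0.52 ± 0.21. The B cell list was called lower at a median of -0.96 (adjusted p = 8.29e-07; Cr2 -1.001 ± 0.42, Blk -0.87 ± 0.37), also with 0 genes by either adjustment. The interferon list was called higher at a median of 0.50 (adjusted p = 9.11e-05; Isg15 0.95 ± 0.53, Oas1a 0.29 ± 0.18), a call lost without WT 4, whose mean of the list was the highest of its group. The acinar list was called lower (adjusted p = 1.73e-15, 12 of 12 genes adjusted over the list alone, Clps -3.62 ± 1.08, Try4 -6.21 ± 2.11), which followed its level in DSS 1 and DSS 3. The mast cell list was called higher (adjusted p = 0.0194, 1 of 7 genes adjusted over the list alone), with Mcpt4 at 0.58 ± 0.17, and lost its call without DSS 2, DSS 3, WT 3 or WT 4 and after rescaling to TPM. The clock list was called higher at a median of 0.12 (adjusted p = 0.0464; 0 genes by either adjustment), with Dbp at 0.77 ± 0.30 and Nr1d1 at 0.76 ± 0.34, and lost its call without DSS 1, DSS 3, WT 1 or WT 4 and after rescaling to TPM. The proliferation list was called higher and the tuft cell, stem cell and eosinophil lists lower (adjusted p = 0.00955, 0.00922, 0.0354 and 0.0181; 0 genes by either adjustment). Proliferation and eosinophil genes lost the call without DSS 2 or WT 2, tuft cell genes without DSS 1, DSS 3 or WT 4 and stem cell genes without DSS 2, DSS 3, WT 3 or WT 4. The purine list was called higher at a median of 0.06 (adjusted p = 0.0194; 0 genes by either adjustment) and lost its call without DSS 2, WT 2 or WT 3. Its members with the smallest p were Xdh (0.53 ± 0.20) and Aprt (0.18 ± 0.07). These 11 lists had adjusted p = 0.528 to 0.866 with an estimated correlation. The histidine list was not called (adjusted p = 0.817; 0 genes by either adjustment), with Carns1 at -0.25 ± 0.13 and Maob at 0.23 ± 0.20.

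The KO group differed from DSS in 22 genes, 13 higher and 9 lower, of which 18 met the naming rule. Dbp rose by 2.42 ± 0.30 (adjusted p = 0.00711), from 1.92 ± 1.01 FPKM in DSS (n = 3) to 14.4 ± 4.03 FPKM in KO (n = 4). Banp fell by 0.89 ± 0.12 (adjusted p = 0.00711). The linker histone gene H1f0 rose by 0.73 ± 0.10 (adjusted p = 0.0116), and Cystm1 rose by 0.81 ± 0.15. The cold-inducible RNA-binding protein gene Rbm3 (0.67 ± 0.12), Ccdc116 (0.75 ± 0.10), Cdkn3 (0.53 ± 0.10), the dynein light chain gene Dynlt1b (0.50 ± 0.09), Ube2m (0.47 ± 0.07), Rbks (0.39 ± 0.07), Sra1 (0.33 ± 0.06), Mrpl2 (0.28 ± 0.05) and Mapk6 (0.27 ± 0.05) also rose. The collagen prolyl hydroxylase gene P4ha1 (-0.49 ± 0.09), the Notch-modifying Lfng (-0.41 ± 0.08), Ints8 (-0.37 ± 0.07), the autophagy kinase gene Ulk2 (-0.37 ± 0.06) and the ion transport kinase gene Wnk1 (-0.33 ± 0.06) fell. The count was 0 without DSS 1 or DSS 3, 4 without KO 4, 5 without DSS 2, 8 without KO 2 and 14 without KO 3, and 0 of the 18 named genes passed with each library left out. The higher and lower calls were 12 and 5 after quantile normalization, and the count was 0 without the acinar-rich libraries. It was 35, 3 higher and 32 lower, without the squamous-rich ones, which left DSS 1 and DSS 3 but not the acinar-rich KO 3.

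Cholesterol synthesis genes were higher in KO than in DSS as a list (adjusted p = 9.88e-12), at a median of 0.56. Of 14 genes, 0 passed over all genes and 10 adjusted over the list alone. Hmgcs1 stood at 0.95 ± 0.23 and the sterol-sensing transcription factor gene Srebf2 at 0.28 ± 0.07. The oxidative phosphorylation list was called higher at a median of 0.19 (adjusted p = 1.66e-08; 0 genes by either adjustment), with Cox7b at 0.30 ± 0.10 and Atp5j at 0.23 ± 0.07. The macrophage list was called lower at a median of -0.62 (adjusted p = 3.17e-05, 3 of 12 genes adjusted over the list alone), with Adgre1 at -0.71 ± 0.23 and Csf1r at -0.71 ± 0.24. The colonocyte list was called higher (adjusted p = 0.00101, 1 of 16 adjusted over the list alone, Vil1 0.37 ± 0.08). The clock list was called higher (adjusted p = 0.00753, 6 higher and 4 lower of 14 genes adjusted over the list alone), with Tef at 1.10 ± 0.24, Hlf at 0.49 ± 0.12 and Arntl at -0.58 ± 0.15, and so was the immediate early list (adjusted p = 0.00753, 2 of 13 adjusted over the list alone, Atf3 0.74 ± 0.16). These 6 lists kept their calls with every library left out. The T and NK cell list was called lower (adjusted p = 0.0164, 1 of 12 adjusted over the list alone, Cd3e -0.81 ± 0.20) and lost its call without KO 2, the library second lowest in Hox genes. The acinar list was called lower (adjusted p = 0.00164), high as it was in DSS 1, DSS 3 and KO 3, and lost its call without DSS 1. MHC class II, NF-kB, B cell and endothelial lists were called lower too, and smooth muscle, enteric neuron and xenobiotic lists higher, with 0 genes by either adjustment (adjusted p = 0.00164 to 0.0471), and each lost its call without at least 1 library. The 15 lists given had adjusted p = 0.655 to 0.695 with an estimated correlation. The purine list was not called (adjusted p = 0.866, 1 of 26 genes adjusted over the list alone), with a negative median of -0.10 beside an upward direction in camera. Aprt stood at 0.28 ± 0.07 and Nt5c2 at 0.33 ± 0.10. Nor was the histidine list (adjusted p = 0.911; 0 genes by either adjustment), with Hars2 at -0.18 ± 0.07 and Aoc1 at -0.71 ± 0.36.

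Limma called 2 genes between COM and DSS, both higher and both output genes of the circadian clock. Dbp rose by 2.85 ± 0.30 (adjusted p = 9.24e-04) and Tef rose by 1.60 ± 0.24 (adjusted p = 0.0404). The clock list was called higher (adjusted p = 1.44e-06, 10 of 14 genes higher and 3 lower adjusted over the list alone, adjusted p = 0.527 with an estimated correlation). Below the threshold over all genes stood Nr1d2 (1.32 ± 0.24), Hlf (0.67 ± 0.12), Arntl (-0.82 ± 0.15), Cry1 (-0.90 ± 0.19) and Npas2 (-0.71 ± 0.15). Gsdmc2 stood at -1.44 ± 0.27 without passing, and so did Lnx1 (0.69 ± 0.11), Rbm3 (0.69 ± 0.12), Ccdc116 (0.59 ± 0.10), Ccdc181 (-0.42 ± 0.08), Alg1 (-0.34 ± 0.07) and Tomm34 (-0.30 ± 0.06). Dbp kept its call with each library left out. Tef lost it without DSS 1, DSS 3 or any COM library. The count was 1 without DSS 1, DSS 3, COM 1, COM 3 or COM 4 and 3 without DSS 2. It was 10 with the COM and DSS libraries alone, 4 after quantile normalization, 1 with a pseudocount of 0.1 or with no filter, 0 without the acinar-rich libraries and 35, 4 higher and 31 lower, without the squamous-rich ones, with the acinar-rich DSS 1 and DSS 3 left.

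**Figure D3:**
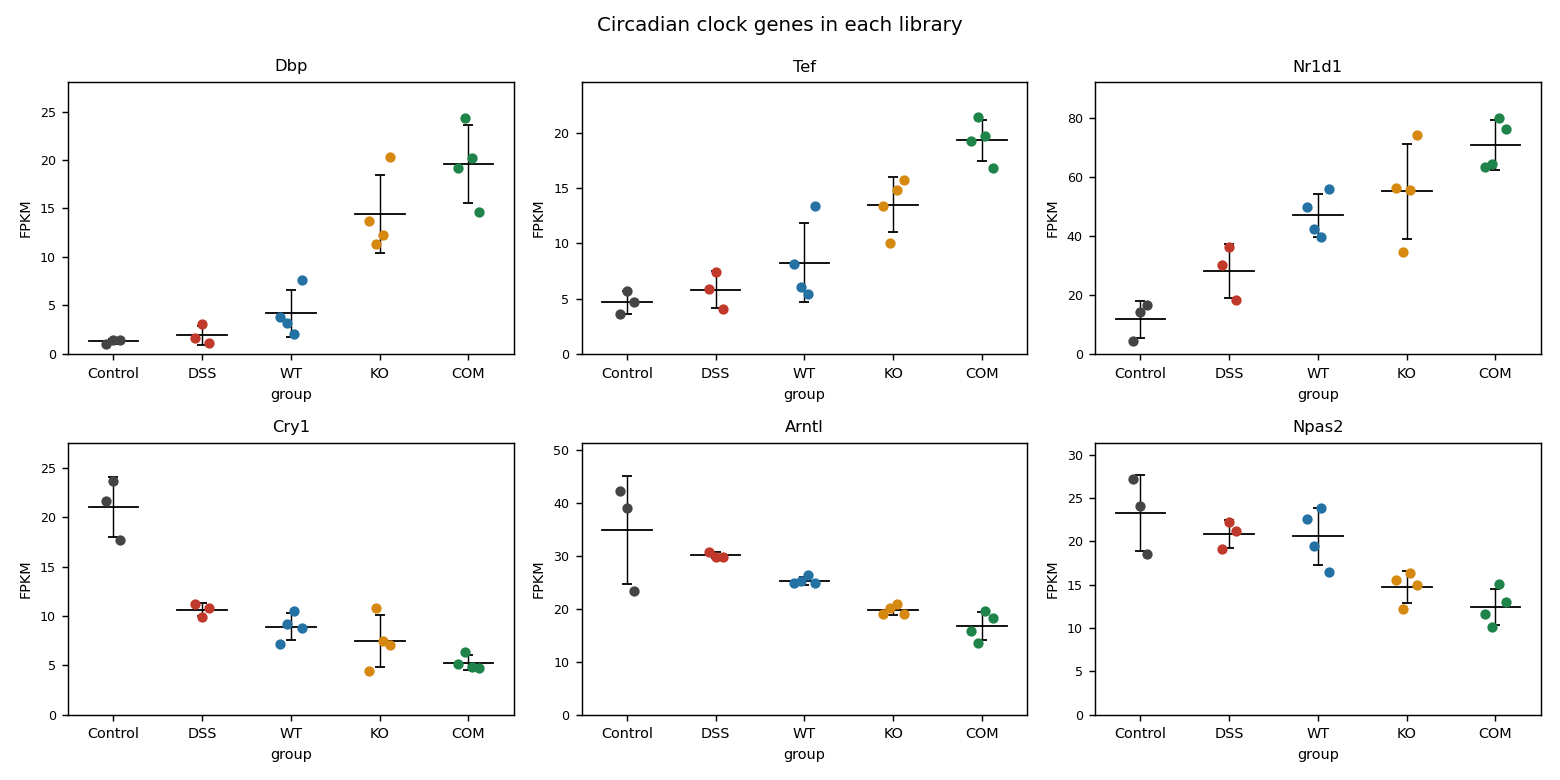
FPKM of 6 circadian clock genes in each library (points) of Control, DSS, WT, KO and COM, with the group mean (line) and SD (bars). Dbp had means of 1.31 FPKM in Control, 1.92 in DSS, 4.17 in WT, 14.4 in KO and 19.6 in COM.

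Other lists of COM against DSS showed 0 genes past the threshold over all genes. The cholesterol list was called higher (adjusted p = 1.44e-06, 4 of 14 genes adjusted over the list alone), with Sqle at 0.64 ± 0.21, Cyp51 at 0.52 ± 0.18 and Sc5d at 0.35 ± 0.11. The xenobiotic list was called higher (adjusted p = 4.68e-04, 0 genes adjusted over the list alone), with Cyp2c55 at 1.34 ± 0.54 and the efflux pump gene Abcb1a at 0.50 ± 0.21. The endothelial list was called lower (adjusted p = 0.00288, 0 genes adjusted over the list alone, Vwf -0.33 ± 0.10, Egfl7 -0.47 ± 0.16). The plasma cell list was called lower (adjusted p = 0.0238, 0 genes adjusted over the list alone, Prdm1 -0.38 ± 0.15, Xbp1 -0.35 ± 0.15) and lost its call without DSS 2. The acinar list was called lower (adjusted p = 4.00e-09, 12 of 12 adjusted over the list alone, Clps -3.67 ± 1.08, Try4 -6.28 ± 2.11), following DSS 1 and DSS 3. Interferon, colonocyte, oxidative phosphorylation and fatty acid oxidation lists were called higher too, and NF-kB, macrophage, B cell, fibroblast and matrix protease lists lower (adjusted p = 0.00186 to 0.0427). Adjusted over the list alone 1 colonocyte gene passed, and all but the B cell list lost their call without DSS 2. The interferon list turned lower without COM 2, at a mean of 5.80 against 3.53 to 3.99 in the other COM libraries, and fatty acid oxidation lost its call without COM 2. The 14 lists given had adjusted p = 0.579 to 0.814 with an estimated correlation. Neither the purine list (adjusted p = 0.962) nor the histidine list (adjusted p = 0.808) was called, with 0 genes by either adjustment. In the purine list Aprt stood at 0.21 ± 0.07 and Nt5c2 at 0.28 ± 0.10, and in the histidine list Hnmt at 0.35 ± 0.15 and Hars2 at -0.14 ± 0.07.

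Between the KO and WT groups, which asks what differs between mice given the KO strain and those given ZJ316, limma called 110 genes, 43 higher and 67 lower in KO. Dbp rose by 1.65 ± 0.28 (adjusted p = 0.0256). H1f0 rose by 0.72 ± 0.10 (adjusted p = 0.0158), and Sox9, a transcription factor gene of crypt progenitors, rose by 0.69 ± 0.13. Banp fell by 0.67 ± 0.11 (adjusted p = 0.0256). Itgam, the integrin gene that marks myeloid cells, fell by 0.74 ± 0.15, and the chaperone gene Hspa8 fell by 0.55 ± 0.11. Golt1a (0.84 ± 0.19), Cystm1 (0.74 ± 0.14), Flywch2 (0.56 ± 0.12), C1qtnf6 (0.56 ± 0.12), Stum (0.55 ± 0.12), Inafm1 (0.47 ± 0.09), the epithelial keratin gene Krt18 (0.46 ± 0.09), Pm20d1 (0.45 ± 0.09) and Mtss2 (0.45 ± 0.09) rose. The lectin receptor gene Clec4a1 (-0.90 ± 0.19), Map3k6 (-0.90 ± 0.16), the chaperone gene Hspa4l (-0.72 ± 0.15), the lysosomal protease gene Ctsc (-0.62 ± 0.14), Ndufb4c (-0.57 ± 0.10), the collagen-modifying Plod2 (-0.56 ± 0.12) and P4ha1 (-0.53 ± 0.08), Hr (-0.53 ± 0.11) and Cited2 (-0.49 ± 0.10) fell. Ndufb4c has near-identical copies. The count was 0 without WT 3, 2 without WT 2, 7 without KO 3, 8 without KO 2, 10 without KO 4 and 14 without WT 1, so that 0 of the 24 named genes passed with each library left out. Rescaling to TPM gave 21 higher and 81 lower calls, quantile normalization 193 calls, the KO and WT libraries alone 467, no filter 51 and a correction for length and GC content 58. The count was 0 without the acinar-rich or the squamous-rich libraries.

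By list, macrophage markers were lower in KO than in WT (1 of 12 past the threshold, 11 adjusted over the list alone, adjusted p = 2.11e-06), with Adgre1 at -0.90 ± 0.21 and Ms4a7 at -0.79 ± 0.19 beside Itgam. The Toll-like receptor and inflammasome list was called lower (adjusted p = 0.0252, 0 of 12 over all genes and 4 adjusted over the list alone, Tlr4 -0.63 ± 0.15, Casp4 -0.49 ± 0.14), a call lost without KO 1 or KO 3. The T and NK cell list was called lower (adjusted p = 0.00851, 0 over all genes and 1 adjusted over the list alone, Cd3e -0.70 ± 0.19), a call lost without WT 4. The smooth muscle list was called higher (adjusted p = 1.15e-05, 0 of 12 over all genes and 4 adjusted over the list alone, Cnn1 0.48 ± 0.12, Des 0.41 ± 0.13), as were the tuft cell list (adjusted p = 0.00600; 0 and 3 of 7; Sh2d6 1.08 ± 0.30) and the cholesterol list (adjusted p = 0.0134; 0 and 1 of 14; Srebf2 0.23 ± 0.06), the latter lost without WT 4 or KO 2. The cytokine and interferon lists were called lower too, and the colonocyte, stem cell, enteric neuron, acinar and oxidative phosphorylation lists higher (adjusted p = 2.11e-06 to 0.0391). Sox9 passed in the stem cell list and 2 colonocyte genes adjusted over the list alone. The interferon, stem cell and acinar lists lost their call without WT 4. The 13 lists given had adjusted p = 0.669 to 0.835 with an estimated correlation. The purine list was not called (adjusted p = 0.234), with 0 genes over all genes and 3 lower of 26 adjusted over the list alone. Xdh stood at -0.76 ± 0.18 and Gda at -0.73 ± 0.18. The histidine list was not called (adjusted p = 0.979; 0 genes by either adjustment), with Carns1 at 0.30 ± 0.12 and Aoc1 at -0.57 ± 0.33.

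The COM group differed from the KO group in 4 genes. Banp rose by 0.87 ± 0.11 (adjusted p = 0.0114), from 4.76 ± 0.542 FPKM in KO to 9.61 ± 1.77 FPKM in COM (n = 4 each). The RNA-binding protein gene Fxr1 rose by 0.33 ± 0.05, and the Integrator subunit gene Ints8 rose by 0.40 ± 0.06 (adjusted p = 0.0464 and 0.0464). The zinc finger gene Zfp414 fell by 0.45 ± 0.07 (adjusted p = 0.0308). Srsf5 (-0.37 ± 0.07), Dpm3 (-0.51 ± 0.10), C1qtnf6 (-0.58 ± 0.12) and Gramd4 (-0.30 ± 0.06) followed by p without passing. No named gene passed with each library left out: Banp lost its call without KO 2, KO 4 or COM 2. The count was 0 without each of these, 1 without KO 1, COM 1 or COM 3 and 2 without KO 3 or COM 4. It was also 0 with the COM and KO libraries alone, 2 after quantile normalization and 1, a higher one, after correction for length and GC content, and 0 without the low-Hox, the acinar-rich or the squamous-rich libraries.

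Several lists of COM against KO were called with 0 genes past the threshold over all genes. The oxidative phosphorylation list was called lower (adjusted p = 2.67e-05, 0 genes adjusted over the list alone, Cox6c -0.31 ± 0.11, Ndufb3 -0.19 ± 0.07), as was the cholesterol list (adjusted p = 0.00385, 1 of 14 adjusted over the list alone, Insig1 -0.65 ± 0.23). The interferon list was called higher (adjusted p = 0.00828, 0 adjusted over the list alone, Gbp2 1.21 ± 0.52), a call lost without KO 1 and turned in direction without COM 2, which held the highest mean of this list, 5.80. The clock list was called higher (adjusted p = 0.0351, 0 adjusted over the list alone, Per1 0.36 ± 0.14, Tef 0.50 ± 0.22), a call lost without KO 1, KO 2, COM 2 or COM 3 and after rescaling to TPM. MHC class II, macrophage and T and NK cell lists were called higher too, and tuft cell, smooth muscle and acinar lists lower, with 0 genes by either adjustment (adjusted p = 0.00385 to 0.0339), and the tuft cell list alone kept its call with each library left out. The 10 lists given had adjusted p = 0.876 with an estimated correlation. The purine list (adjusted p = 0.748) and the histidine list (adjusted p = 0.622) were not called, with 0 genes by either adjustment. The purine members with the smallest p were Impdh1 (-0.40 ± 0.16) and Gda (0.33 ± 0.18), and the histidine members were Aoc1 (0.56 ± 0.33) and Hnmt (0.18 ± 0.14).

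Between COM and WT limma called 1 gene. Dbp rose by 2.08 ± 0.28 (adjusted p = 0.0201), from 4.17 ± 2.44 FPKM in WT to 19.6 ± 3.98 FPKM in COM (n = 4 each). Tef stood at 1.20 ± 0.22 without passing (adjusted p = 0.118). Next by p were Lnx1 (0.59 ± 0.10), the serine racemase gene Srr (0.37 ± 0.07), Nf1 (0.25 ± 0.05), Srsf5 (-0.38 ± 0.07), Map3k6 (-0.79 ± 0.16), Ddx41 (-0.25 ± 0.05), Ints10 (-0.34 ± 0.07) and Spidr (-0.28 ± 0.06). The clock list was called higher (adjusted p = 4.99e-04, 8 of 14 higher and 3 lower adjusted over the list alone, Npas2 -0.68 ± 0.14, Cry2 0.56 ± 0.12). The macrophage list was called lower (adjusted p = 4.99e-04, 0 adjusted over the list alone, Adgre1 -0.61 ± 0.21, Cx3cr1 -0.62 ± 0.22), as was the plasma cell list (adjusted p = 0.0189, 2 of 7 adjusted over the list alone, Xbp1 -0.39 ± 0.14, Prdm1 -0.39 ± 0.14), the latter lost without WT 3. The xenobiotic list was called higher (adjusted p = 0.00548, 3 of 13 adjusted over the list alone), with Cyp2c55 at 1.52 ± 0.50, Abcb1a at 0.60 ± 0.19 and Ces2a at 0.53 ± 0.18. Mast cell and proliferation lists were called lower too, and colonocyte, smooth muscle, enteric neuron and fatty acid oxidation lists higher, with 0 genes by either adjustment (adjusted p = 0.00168 to 0.0384). The colonocyte and fatty acid oxidation lists kept their calls with each library left out. Of these 8 libraries COM 1 and COM 2 had the highest means of fatty acid oxidation genes (4.27 and 4.94) and of adipocyte genes (4.32 and 5.12), as they had of the COM and DSS libraries. The 10 lists given had adjusted p = 0.596 to 0.788 with an estimated correlation. The purine list (adjusted p = 0.0608) and the histidine list (adjusted p = 0.606) were not called, with 0 genes by either adjustment. Their smallest p belonged to Prps1 (-0.49 ± 0.15) and Adsl (-0.25 ± 0.09), and to Hnmt (0.40 ± 0.14) and Carns1 (0.19 ± 0.12). The call of Dbp was lost without WT 1, WT 2, WT 3, COM 1, COM 2 or COM 3. With the COM and WT libraries alone, with a pseudocount of 0.1 and without the squamous-rich libraries the count was 0. It was 24 without WT 4 and 2 with no filter.

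Across the 13263 tested genes, the changes of each strain against DSS were set against the change of DSS against Control. Both comparisons use the DSS libraries, which alone favours opposite signs. Of the 1539 genes higher in DSS, 92.7% had the opposite sign in KO against DSS, 90.2% in COM and 62.6% in WT, and of the 704 lower genes 93.0%, 90.2% and 59.4%. In 100 simulated draws with no change in any group, equal numbers of genes most extreme in DSS gave mean shares of 82.2%, 83.3% and 81.7% for the higher and 85.7%, 86.7% and 86.5% for the lower genes, and shares as high as observed arose in 30, 37 and 89 and in 42, 46 and 94 draws. In 100 draws with the observed DSS change in all groups of DSS-treated mice, the genes called gave 60.8%, 61.1% and 62.8% for the higher and 64.0%, 65.1% and 66.1% for the lower genes, and shares as high arose in 0, 4 and 57 and in 0, 1 and 73 draws. These draws called a mean of 1913.5 genes higher in DSS, more than observed, so they may understate the shares that arise without an effect of the strains. Across genes, which are not independent replicates, Pearson's r was -0.77 for KO, -0.74 for COM and -0.49 for WT, against -0.47 (SD 0.30), -0.52 (SD 0.25) and -0.48 (SD 0.28) for simulated unchanged groups, of which 14, 22 and 55 of 100 draws were as negative. The covariances were -0.095, -0.107 and -0.064, against simulated values of -0.028, -0.031 and -0.029, with 2, 2 and 10 draws as negative. Among called genes, 5 higher and 6 lower in DSS were called the opposite way in KO, and 0 in WT or COM. KO against DSS had 0 calls without DSS 1 or DSS 3. Independent lists would share 1.04 and 0.69, which leaves out that both use the DSS libraries, and with the DSS change in all groups as many arose in 1 of 100 draws for either direction. The 5 were Lfng, Ulk2, Wnk1 and, chosen after their values were seen, Cldn10 and Pappa. The 3 DSS libraries cannot be split into parts of at least 2, so part of these values may come from sharing them.

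The changes of the strains against DSS were also compared with each other. Pearson's r across genes was 0.77 for WT and COM, 0.74 for KO and COM and 0.56 for WT and KO, against 0.55 (SD 0.25), 0.50 (SD 0.29) and 0.51 (SD 0.26) for simulated unchanged groups, of which 20, 27 and 52 of 100 draws were as high. The covariances were 0.072, 0.065 and 0.044 against 0.030, 0.027 and 0.027, with 9, 12 and 17 draws as high. Dbp was the 1 gene called higher in both KO and COM against DSS. Against Control, 1218 of the genes higher in DSS were also called higher in WT, 388 in KO and 574 in COM, and 559, 117 and 203 of the lower genes were called lower. Independent lists would share 226, 56.7 and 80.9 higher and 58.8, 10.2 and 16.5 lower genes. Simulated unchanged groups share 0 to 0.01 but call almost no genes, so part of the overlap may come from the shared Control libraries. The number called in all 4 comparisons with Control was 290 higher and 70 lower.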

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

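The search for single libraries far from the other 3 of their group was planned, but the levels searched were those of genes and lists chosen for the text after the results were seen. It covered 29 list means in WT, KO and COM (87 groups) and 18 gene levels, each in those of these groups in its own comparisons (29 groups), and 9 of the 116 had a library beyond the critical value of Dixon's test, against 5.8 expected by chance.

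Gsdmc2 lay at 265 FPKM in COM 3, above 234 to 238 FPKM in the other COM libraries. Pla2g4c lay at 5.02 FPKM in WT 3, above 0.41 to 1.12 FPKM in the other WT libraries. The mean log2(FPKM + 1) of the endothelial genes was 2.46 in WT 2, below 2.63 to 2.66 in the others of its group. That of the NF-kB targets and regulators was 3.92 in KO 2, below 4.20 to 4.25. The interferon response had a mean of 5.00 in WT 4, above 4.15 to 4.19. The neutrophil markers had a mean of 2.73 in COM 3, above 1.51 to 1.72, and the squamous epithelium genes had a mean of 4.01 in the same library, above 1.14 to 1.19. The pancreatic acinar genes had a mean of 9.55 in KO 3, above 1.07 to 1.22. The purine metabolism genes had a mean of 4.42 in COM 2, above 4.17 to 4.20.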

How the results depend on the processing

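The exclusions by marker genes and the length and GC correction were chosen after seeing the data, and the other alternatives were planned. Every call count but that of WT against DSS moved by more than 1.5 times under at least 5 alternatives. Correlations between comparisons moved by less than the wide simulated SD (0.25 to 0.30), but were not run under unplanned settings. Named genes were not tested under these or the fold threshold. Of their 5461 values, 4529 stayed on their side of the threshold, 882 fell below it, 50 passed it and 0 reversed. In the others 42 of 259 called genes stayed called. Where no reason is given, the cause was not tested.

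With each library left out in turn, DSS against Control gave 1266 to 3662 genes, WT against Control 1873 to 4624, KO against Control 254 to 1591 and COM against Control 402 to 2302. WT against DSS gave 0 to 0, KO against DSS 0 to 19, COM against DSS 1 to 3, KO against WT 0 to 159, COM against KO 0 to 2 and COM against WT 0 to 24. The gene lists called numbered 129 to 157. The correlation with the DSS change ran from -0.64 to -0.37 for WT, from -0.82 to -0.63 for KO and from -0.80 to -0.65 for COM. Between strains it ran from 0.42 to 0.77 for WT and KO, from 0.68 to 0.88 for WT and COM and from 0.67 to 0.86 for KO and COM.

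The 5-group model assumes equal spread, but pairs of Control libraries correlated at 0.926 to 0.984 and WT ones at 0.990 to 0.992. With only the groups compared, counts were 0, 1016, 2 and 15 for DSS, WT, KO and COM against Control. They were 10 each for KO and COM against DSS, 467 for KO against WT and 0 for COM against KO or WT. With an absolute log2 fold change of at least 1, which drops smaller changes by construction, they were 282, 299, 70 and 94 for DSS, WT, KO and COM against Control, 1 for KO against DSS, 1 for KO against WT and 0 for COM against KO. A pseudocount of 0.1 gave 1 gene for COM against DSS and 0 for COM against WT. No filter gave 1 for COM against DSS, 2 for COM against WT and 51 for KO against WT, and the stricter filter gave 39 for KO against DSS. Quantile normalization gave 4 for COM against DSS, 2 for COM against KO and 193 for KO against WT. With an estimated correlation 0 gene lists were called by camera in place of 142. Of the 142, 129 were called the same way after quantile normalization and 132 after rescaling to TPM, and no median changed sign. With each library left out, 69 of them kept their call, the libraries given for several lists together not being all that ended one, and 4 turned in direction without 1 library.

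Without DSS 1, DSS 3 and KO 3, the libraries rich in acinar transcripts, counts were 426 for DSS against Control, 268 for KO against Control, and 0 for KO against DSS, COM against DSS, KO against WT and COM against KO. Without DSS 2, WT 2, WT 4, KO 3 and COM 3, rich in squamous transcripts, they were 309, 751, 159 and 63 for DSS, WT, KO and COM against Control, 27 (0 higher and 27 lower), 35 (3 and 32) and 35 (4 and 31) for WT, KO and COM against DSS, whose group was then the acinar-rich DSS 1 and DSS 3, and 0 for KO against WT, COM against KO and COM against WT. Without Control 3 and KO 2, with low Hox genes, COM against KO gave 0. Removing the trend on transcript length and GC content gave 58 for KO against WT and 1 for COM against KO. Without the acinar-rich libraries DSS 2 alone stood for the DSS group and was assumed to vary like the other groups.

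The labels do not say that equal replicate numbers mark shared cages or days. Deviations of same-numbered libraries from their group means had a median correlation of 0.013, 13 of 33 pairs were over 0.1, and 3 of 18 libraries correlated best with a library of their own number. With the replicate number as a block, counts were 557 for COM against Control, 361 for KO against Control, 7 for KO against DSS, 1 for COM against DSS, 10 for KO against WT and 0 for COM against KO, and the others stayed within 1.5 times. The number of reads per library is unknown, so no limit of detection can be given for low genes, and the alternative planned for read counts was not run, as the values are FPKM.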

Other observations

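The tests of the share of epithelium, of the time of collection and of the size of changes after the length and GC correction were chosen only after the result was seen, and the other tests were set before it.

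Secretory and signalling genes outside the lists described so far also differed between DSS and Control, although camera called none of these lists with the settings of the report. After quantile normalization it called the goblet cell (adjusted p = 0.00647) and antimicrobial (adjusted p = 0.00262) lists higher. The mucus genes Clca1 and Fcgbp rose by 1.52 ± 0.33 and 1.36 ± 0.25 (2 of 13 goblet cell genes, 3 adjusted over the list alone, camera adjusted p = 0.0852), and Clca1 stood at 1.01 without Control 3. Among 15 epithelial antimicrobial genes 3 rose (3 adjusted over the list alone, camera adjusted p = 0.0684), Ang4, Nos2 by 2.11 ± 0.58 and the iron-sequestering Lcn2 by 1.55 ± 0.32. The tryptophan-degrading Kmo, Kynu and Il4i1 and the aryl hydrocarbon receptor gene Ahr rose by 1.06 ± 0.26, 0.75 ± 0.20, 0.98 ± 0.29 and 0.40 ± 0.13 (4 of 8, 4 adjusted over the list alone, camera adjusted p = 0.109), with Il4i1 at 0.52 and Ahr at 0.21 without Control 3.

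Purinergic receptors, which bind nucleotides and adenosine, rose in 4 of 12 cases in DSS (5 adjusted over the list alone, camera adjusted p = 0.0637): P2rx7 by 0.76 ± 0.14, P2ry12 by 0.67 ± 0.15, Adora1 by 0.59 ± 0.16 and Adora2a by 0.49 ± 0.12. The ATP-release channel gene Panx1, named after its values were seen, fell by 0.44 ± 0.11 (1 gene, 1 adjusted over the list alone). The eosinophil chemokine gene Ccl11 rose by 1.30 ± 0.19 in DSS, 1.02 ± 0.18 in WT, 1.31 ± 0.18 in KO and 1.25 ± 0.18 in COM against Control, and the eosinophil ribonuclease gene Ear2 by 1.15 ± 0.26 in DSS (2 of 5 eosinophil genes, 2 adjusted over the list alone, camera adjusted p = 0.0663). Clock genes differed between DSS and Control too, as Nr1d1 rose by 1.32 ± 0.36 (0.80 without Control 1) and Cry1 and Cry2 fell by 0.91 ± 0.20 and 0.44 ± 0.14.

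By its Hox genes, Control 3 may come from another part of the colon. Against Control 1 and 2 alone, all 2243 genes called between DSS and Control kept their sign. Their median change was 85.3% (bootstrap SD over genes 1.06) of that with all 3, 0.43 in place of 0.51. Selection used Control 3, so this does not decide. The 1184 still called argue against Control 3 as the whole cause. For the 8 called colonocyte and xenobiotic genes the change was 70.7% (SD 5.54), 0.54 in place of 0.76, with 4 still called. This leaves Control 3 open for them. Removing a trend on transcript length and GC content left 2124 calls where 2242 stood without it, 1740 of them in both, and the 2242 genes all kept their sign at 93.0% (SD 1.01) of their median change, which argues against the trend as the whole cause but not as part of the balance of higher and lower calls, 1199 and 925 after it. A lower share of epithelium alone would raise all other cell types alike, whereas the endothelial and smooth muscle medians, 0.94 and -0.39, lay 1.33 apart with deviations of 0.17 and 0.09. DSS itself, the gavage, which the labels' protocol mentions only for DSS-treated mice, and a change in other cell types stay open, as the design does not separate them.

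Clock genes in COM against DSS may reflect another time of day at collection, which the labels do not give. Of 32 values of 8 clock genes in the 4 COM libraries, 32 lay outside the DSS range on the side named, against 28 in KO and 19 in WT. If each group was collected together, time and strain cannot be told apart. A glucocorticoid response at collection is argued against, since its 8 genes had a median change of 0.00626 (median absolute deviation 0.18) and 2 of them stood at 0.3 or more. So does an effect of the strain.

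Pancreatic acinar genes in DSS 1, DSS 3 and KO 3 may come from pancreas collected with the colon, and their 12 values correlated at 0.975 or more between these libraries. Of 3 islet genes 0 met the bound set for pancreas, 2 being in the table: Ins2 lay at 2.89 FPKM in DSS 1, 0.43 in KO 3 and 0 elsewhere, and Iapp reached 2.68 FPKM in Control 3. Islets are a small part of pancreas, so this does not decide. In 3 of 15 libraries of DSS-treated mice the list mean lay at least 1 log2 unit above all Control libraries, and expression of these genes by colon cells was not tested.

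Other splits of the same libraries into groups of these sizes were fitted for each comparison. For DSS against Control the 10 splits are too few for a share under 0.05, and 1 of them, the real one, gave 2243 genes, with 1 gene as the highest of the others. Over 10 comparisons a share under 0.05 does not exclude chance. It arose for WT against Control (1 of 35 splits as large: 3058 genes, highest other 394), COM against Control (1 of 35: 1008, 606), KO against WT (1 of 35: 110, 4), COM against KO (1 of 35: 4, 0) and COM against DSS (1 of 35: 2, 1). The splits were not fitted with other settings, some of which brought the real count to the highest other or below. A library left out did so for all but WT against Control (402 without COM 3, 0 without WT 3, 0 without KO 2 and 1 without DSS 1). Other splits may lose calls too, so this does not decide. With 0 genes called in WT against DSS all 35 of 35 splits gave as many (highest other 1), so they say nothing about chance. Another split gave more for KO against DSS (2 of 35: 22, 34), KO against Control (2 of 35: 682, 811) and COM against WT (3 of 35: 1, 10). The 34 genes arose where DSS 1, DSS 3 and KO 3, all rich in acinar transcripts, were set against the rest. The 10 genes of COM against WT, where WT 4 took the place of COM 2, are several times the real count and may point to a structure of the samples, which was not tested.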
